A study of Mus musculus with 2 samples.

How the data were processed

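H3K36me3 was profiled by chromatin immunoprecipitation and sequencing in liver of embryonic day 16.5 mice, in 2 biological replicates of 1 group. The deposited files are 4 peak lists in the narrowPeak format on the mm10 assembly, per the deposited descriptions of the files. They are a list for each replicate, a list from both replicates pooled and a list of replicated peaks. Each replicate's list was derived from that replicate's alignments together with 2 other files, and the replicated list from the 3 other lists, per the same descriptions. The aligner, the peak caller, its version and settings, and the rule by which a peak counted as replicated are not given in the sources used here. The control libraries were not analysed here. In all of the lists the lowest −log10 p was just above 2 and a −log10 q of 2 was reached by 86.3% of the peaks of replicate 1, 72.7% of replicate 2 and 74.1% of the pooled list, so the deposited threshold was permissive.

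The deposited columns used were the position of each peak, its fold enrichment (a linear ratio by the authors, whose denominator is not given in the sources used here) and its −log10 p and −log10 q, which the authors gave per peak. The deposited display score, from 10 to 1000, and the summit position were read but entered no result. Fold and p are values of a peak within its list and were used to describe, rank or filter peaks in that list and, in the closing section, to compare the folds of peaks of X and autosomes and of gene sets within a list. No read counts were among the files, so depth is unknown and no interval that needs it is given. The replicates differ in how much was called, and whether they differ in depth could not be seen. A narrow-peak list of a broad mark breaks domains into pieces, so coverage by peaks is a lower estimate of the extent of the mark and depends on the caller's threshold.

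Gene models were those of GENCODE M21 for GRCm38, the assembly that mm10 names. Chromosome lengths were checked against the genome sequence. Measures of genes used chromosomes 1 to 19 and X, with 21728 protein-coding genes, each from its first to its last annotated base. Of these, 10167 overlap another gene. Coverage of a gene is the percent of its body under the union of the peaks of a replicate. A gene was called marked at 10% or more in both replicates. Peaks were called shared at an overlap of at least 50% of their own length, and counts at 1 bp were checked against bedtools 2.31.1, which gave the same numbers. The other list was shifted 100 times along each chromosome for the chance level. For the alternative of 50% of both peaks, the chance level was computed with the rule of 50% of the peak's own length, which bounds it from above. Gene body enrichment used 1000 circular shifts. Shape was measured in marked genes of at least 10 kb, in 10 equal parts, in the 1 kb centred on the start site and in internal exons against introns, with a sign-flip permutation test over 20 chromosomes (100000 resamples). A gene's presence among the marked ones depends on the same peaks, and the alternative in which genes were chosen in the other replicate addresses this only in part. Coverage in the replicates had a Pearson correlation of 0.968 across genes, so genes chosen there also have covered bodies in the measured replicate. Domains were replicated peaks joined across gaps of at most 3 kb.

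The gene lists, the 10% minimum and the rule for named genes were fixed before the data were examined. The rule names the 3 highest and the lowest member of each list, the 10 genes of at least 10 kb with the highest mean coverage, the 5 with the largest difference between replicates in each direction, the 5 longest domains and the 5 replicated peaks of highest fold. For lists in which more than 3 members were at 0, members tied at 0 are not named one by one, and for the lists of cell types and families with little coverage the highest are given across lists. Lists were tested against 10000 random lists from the same part of gene length (10 equal parts of all genes by length), two-sided, with Benjamini-Hochberg adjustment over 40 sets at 0.05. Of the listed symbols, 6 were unmatched. C5, Whsc1 and Whsc1l1 are not in the annotation under these symbols, and H19, Meg3 and 5530601H04Rik are not protein-coding. The X chromosome was ranked among 20 chromosomes.

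The functions were tested on simulated peaks on the 21728 annotated genes. For gene list coverage, 97 of 100 genes planted at 30% and 97 of 100 planted at 60% were measured within 5 points. All 100 simulated lists of 10 genes with 5 planted members were found at each level, at an unadjusted p below 0.05. Of 100 lists without planted genes, 4 were called at that p. These counts hold for the simulated peaks only. In the measured data, most random lists matched to the 10 proteasome genes had means between 1.23% and 20.3%. How often a list with 5 members at 30% would be found there was not tested. For the closing section, strata of GC content returned planted exon minus intron differences of 0 and 20 points within 2 points.

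Alternatives were a −log10 q of at least 2, the strongest peaks only (as many as make up 50% of the shorter list), the pooled or the replicated list, each replicate alone, peaks joined across 1 kb, other overlaps, gaps, gene length minimums and statistics, and genes that overlap no other gene. Exons against introns and X against autosomes on unmasked bases, and genes chosen in the other replicate, were added after the data were seen. Non-coding genes entered no comparison of coverage. Peaks on chromosome Y (12 in replicate 1, 3 in replicate 2) and on scaffolds (10 and 17) entered the peak counts, covered lengths and observed shares of shared peaks. They entered neither the shifted placements nor any measure of genes. Peaks on Y also entered the sequence shared by the replicates and the domains. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.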

Results

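Trimethylation of lysine 36 of histone H3 (H3K36me3), a mark that the SETD2 enzyme lays down along genes as RNA polymerase II transcribes them, was measured by chromatin immunoprecipitation and sequencing in mouse embryonic liver. The livers were taken at embryonic day 16.5 from mixed-sex pools of the B6NCrl strain. At this age the liver holds blood-forming cells, most of them of the red cell lineage, beside the hepatocytes. The series has 1 group of 2 biological replicates. Replicate 2 came from the livers of 41 embryos, and replicate 1 from a pool whose size is not stated. There is no other tissue, stage or treatment in the series, so no groups were compared. The question the data can answer is where the mark lay along the genome, and on which genes, with the difference between the replicates as the error. Values given with ± are the mean and SD of the replicates, n = 2, unless another number is stated. The data are lists of peaks on the mm10 build, so the number of reads behind each peak is unknown.

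The deposited list of replicate 1 held 112625 peaks that covered 53.5 Mb, and that of replicate 2 held 100515 peaks that covered 38.2 Mb. The covered length was 45.9 ± 10.8 Mb. Peaks were narrow, with a median width of 314 bp in replicate 1 and 272 bp in replicate 2. The authors' fold enrichment ranged from 1.70 to 23.3 in replicate 1 and from 1.59 to 21.3 in replicate 2. The authors' list of replicated peaks held 69676 peaks that covered 43.3 Mb.

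The replicates shared 27.5 Mb of covered sequence, a Jaccard index of 0.429. Of the bases covered in replicate 2, 72.0% were also covered in replicate 1, and of those covered in replicate 1, 51.4% were covered in replicate 2. At least 50% of the length was covered by the other replicate for 42.2% of the peaks of replicate 1 and for 66.1% of the peaks of replicate 2. When the overlap had to reach 50% of both peaks, these shares were 30.7% and 34.4%. When the lists were shifted along the chromosomes against each other, 1.56% and 2.28% of peaks were shared on average (permutation p = 0.0099 for each, the smallest that 100 shifts can give). The share fell with the rank of the peak within its list. When each list was divided by p into 10 equal parts, 85.7% of the peaks of replicate 1 and 96.8% of those of replicate 2 were shared in the strongest part, and 21.8% and 43.6% in the weakest.

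**Figure D1:**
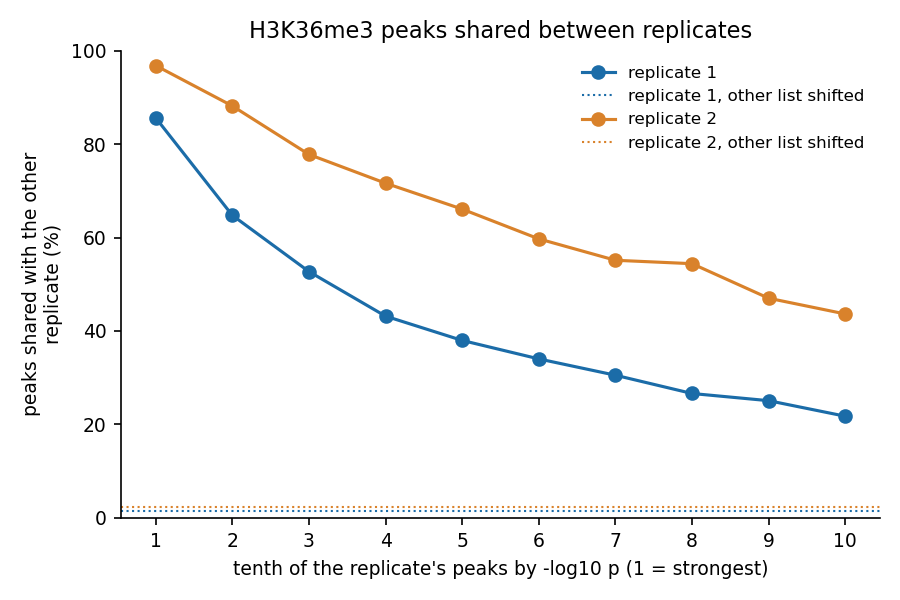
Percent of the peaks of each replicate with at least 50% of their length covered by peaks of the other replicate (y axis), in 10 equal parts of the list ranked by the authors' −log10 p (x axis, 1 is the strongest). Lines with points are the replicates and dotted lines are the mean of 100 shifted placements. Replicate 2 lies above replicate 1 in every part, from 96.8% down to 43.6%.

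Of 21728 protein-coding genes, 4300 had at least 10% of the gene body covered by peaks in both replicates and are called marked here. A further 1016 genes passed 10% in replicate 1 alone and 109 in replicate 2 alone. No base was covered in either replicate in 11870 genes (54.6%). Among the marked genes, 4021 had higher coverage in replicate 1, and the median excess was 8.82 percentage points. Across genes, which are not independent replicates, coverage in the replicates had a Spearman correlation of 0.935 and a Pearson correlation of 0.968. The number of marked genes depended on the minimum coverage, with 8541 genes at any overlap and 2083 at 25%.

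The most fully covered genes of at least 10 kb were Slc2a1, Top2a and Ncapd2. Slc2a1, the glucose transporter of red cells and many other cells (chromosome 4, 119108711 to 119137983), was covered over 90.6 ± 4.35% of its body. Top2a, the topoisomerase of dividing cells (chromosome 11, 98992943 to 99024189), was covered over 89.5 ± 6.59%, and Ncapd2, a condensin subunit (chromosome 6, 125168007 to 125191701), over 88.8 ± 3.96%. The next were the cyclin gene Ccnf (84.7 ± 3.02%), the translation regulator Eif4g2 (83.6 ± 2.84%), the mitotic kinase gene Aurka (83.3 ± 4.07%), the RNA-binding protein gene Rbm38 (83.3 ± 2.41%), the uridylyltransferase gene Tut7 (82.8 ± 6.65%), the phosphate transporter gene Slc20a1 (82.0 ± 6.02%) and the splicing regulator Rbm5 (82.0 ± 7.71%). The genes with the largest excess in replicate 1 were Ddx52 (57.7% against 24.7%), Tsr1 (71.4% against 39.1%), Ilf2 (67.1% against 36.6%), Timm17a (44.6% against 15.7%) and Haus6 (47.3% against 18.4%). The largest excesses in replicate 2 were smaller, at 14.2 points in Letmd1, 11.6 in Trim56, 9.99 in Timm9, 9.46 in Kctd2 and 9.37 in Rela.

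To ask which cell types and processes the marked genes belonged to, 34 gene lists and 6 gene families were fixed before the data were examined, and the mean coverage of each was set against 10000 random lists of the same size and gene length. This is a two-sided permutation test with Benjamini-Hochberg adjustment over the 40 lists and families. It describes these samples, since genes are not replicates of the tissue. Coverage was higher than in random lists for 13, lower for 11, and passed the adjusted threshold in neither direction for 16. The smallest adjusted p the permutation test could give here was 0.000533. The fixed lists held 354 symbols, of which 6 had no match among the protein-coding genes.

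The lists chosen for the red cell lineage were among the most covered, and whether their members are restricted to red cells in this tissue was not tested. All 13 genes of the erythroid cytoskeleton and membrane were marked, with a mean coverage of 57.2 ± 7.65% against 7.95% in random lists (permutation adjusted p = 0.000533). Slc4a1, the band 3 anion exchanger (chromosome 11, 102348824 to 102366203), was covered over 81.1 ± 3.15%, Epb42 over 79.7 ± 6.79% and Kel, the Kell antigen, over 70.0 ± 10.99%, and the lowest member was the adducin gene Add2 at 31.0 ± 5.71%. All 11 genes of haem synthesis were marked, at 52.9 ± 5.36% (permutation adjusted p = 0.000533). The highest were the mitochondrial transporter gene Abcb10 at 81.1 ± 4.11%, whose body lies wholly within another annotated coding gene, Fech, the ferrochelatase, at 70.1 ± 6.10% and Ppox at 67.5 ± 9.35%. The lowest was Cpox at 17.8 ± 3.75%. Of 11 erythroid transcription factors and regulators, 8 were marked in both replicates, with a mean of 37.8 ± 5.42% (permutation adjusted p = 0.000533). Tfrc, the transferrin receptor (chromosome 16, 32608920 to 32632794), was covered over 77.6 ± 5.32%, the erythropoietin receptor Epor over 61.1 ± 9.68% and Lmo2 over 54.8 ± 7.20%. Of the body of Lmo2, 62.5% lies within another coding gene, and the rest was covered over 33.6 ± 10.6%. The 3 members not marked in both replicates were Gata1 (12.3 ± 3.58%), Bcl11a (6.35 ± 3.09%) and Myb (5.601 ± 0.184%). The globin genes themselves, which are short (0.955 kb for Hba-a1), passed no test. None of the 4 adult globins was marked in both replicates, and only Hbb-bt held a peak, in replicate 1 alone (13.5% of its 1.47 kb). No embryonic globin had a covered base. For both globin lists the range of random lists began at 0%, so no lower call could have been made.

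Genes of cell division and of basic cell functions were also covered. The 10 mitosis genes were all marked, with the highest mean of any list at 67.7 ± 7.55%. They were led by Top2a, by Aurka and by Plk1 (76.2 ± 7.01%), and the lowest was Ttk (28.0 ± 7.45%). Of 12 DNA replication genes, 10 were marked, with a mean of 52.8 ± 8.89%. The helicase genes Mcm2 (80.9 ± 7.45%), Mcm5 (80.4 ± 5.598%) and Mcm3 (72.9 ± 13.6%) were the highest, and the X-linked polymerase gene Pola1 (1.196 ± 0.911%) the lowest. All 12 splicing factor genes were marked, at 58.1 ± 9.56%, from Prpf8 (74.5 ± 6.92%), Sf3a1 (71.8 ± 8.16%) and Hnrnpa1 (70.3 ± 8.80%) down to Srsf1 (42.6 ± 9.55%). Of 14 cytosolic ribosomal protein genes, 12 were marked, at 42.4 ± 7.27%, from Rps3 (76.9 ± 5.99%), Rps5 (70.4 ± 4.44%) and Rpl5 (65.1 ± 12.4%) down to Rps2 (12.5 ± 4.13%). Of 10 proteasome genes, 8 were marked, at 35.6 ± 7.43%, with Psmc1 (59.1 ± 9.52%), Psma1 (55.1 ± 8.66%) and Psmc4 (43.0 ± 3.18%) highest and Psmd14 (2.02 ± 1.23%) lowest. All 11 oxidative phosphorylation genes were marked, at 39.4 ± 6.02%, from Atp5b (72.0 ± 7.94%), Atp5a1 (64.5 ± 5.63%) and Uqcrc1 (47.6 ± 3.96%) down to Cox5a (17.1 ± 6.76%). The mitochondrial ribosomal protein family had 37 of 78 members marked, at 16.0 ± 5.005%, with Mrpl22 (46.8 ± 11.9%), Mrpl18 (45.0 ± 8.08%) and Mrps7 (41.6 ± 8.01%) highest and Mrps34 at 0%. Each of these 7 sets had a permutation adjusted p of 0.000533.

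Coverage was also higher than in random lists for 3 further sets. Of 9 genes of autophagy and mitochondrial clearance, 6 were marked, at 29.9 ± 5.82% (permutation adjusted p = 0.00141). The highest were Ulk1 (57.1 ± 13.6%), Becn1 (51.0 ± 7.52%) and Map1lc3b (45.8 ± 13.1%), and the lowest was Atg7 (0.747 ± 0.148%). Of the body of Becn1, 63.5% lies within another coding gene, Cntd1, and the rest was covered over 24.8 ± 7.96%. Map1lc3b lies wholly within other annotated coding genes. Of 14 writers, readers and erasers of H3K36 methylation, 8 were marked, at 20.6 ± 5.78% (permutation adjusted p = 0.00178). The demethylase gene Kdm4a was covered over 56.6 ± 4.44%, Morf4l1 over 38.3 ± 11.8% and Psip1 over 35.5 ± 19.2%, and Dnmt3b held no covered base. Of 11 cholesterol synthesis genes, 10 were marked, at 24.9 ± 6.89% (permutation adjusted p = 0.0310). Hmgcr, the rate-limiting reductase, was covered over 57.0 ± 12.6%, Sqle over 35.7 ± 10.3% and Srebf2 over 30.9 ± 6.10%, and the lowest was Hmgcs1 (9.55 ± 1.72%). The cholesterol call was lost without replicate 1, at a mean of 20.0% (permutation adjusted p = 0.0566), and with the strongest peaks only, at 16.7% (permutation adjusted p = 0.0897). Restricted to genes that overlap no other gene, which leaves fewer genes in each list, the calls were lost for oxidative phosphorylation (mean 34.5%, permutation adjusted p = 0.0604), cholesterol synthesis (mean 33.3%, permutation adjusted p = 0.0604) and the H3K36 set (mean 14.9%, permutation adjusted p = 0.198).

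None of the 5 lists of hepatocyte genes passed the threshold in either direction. The 18 secreted proteins of fetal hepatocytes had a mean coverage of 2.95 ± 1.18% against 8.22% in random lists (permutation adjusted p = 0.132), and 1 of them was marked. The highest were the apolipoprotein gene Apoe (21.4 ± 4.18%), Ambp (15.4 ± 8.93%) and Apob (5.91 ± 1.07%), and Vtn held no covered base. Alb, Afp and Ttr, which encode albumin, alpha-fetoprotein and transthyretin and were singled out after their values were seen, also had no covered base in either replicate. The 11 hepatocyte transcription factors were at 0.711 ± 0.773% against 7.53% in random lists, with none marked (permutation adjusted p = 0.0595). Cebpa was the highest (4.46 ± 6.30%), followed by Nr1h4 (1.31 ± 0.229%) and Hnf1a (0.692 ± 0.978%), and Tbx3 was at 0%. That list was lower than random lists under 5 alternatives, including without replicate 1, where its mean was 0.164%. Of 15 genes of perinatal and adult hepatocyte metabolism, at 3.63 ± 0.923% against 8.68% in random lists (permutation adjusted p = 0.220), only the bile acid transporter gene Slc10a1 was marked (40.3 ± 6.87%). Hpd (7.11 ± 4.45%), which lies wholly within another annotated coding gene, and Aldob (4.96 ± 0.934%) followed, and Ugt1a1 was at 0%. The 7 urea cycle genes had a mean of 6.39 ± 0.670% against 8.96% in random lists (permutation adjusted p = 0.788), with Asl (11.6 ± 0.633%) marked, Ass1 (11.2 ± 1.93%) and Slc25a15 (9.77 ± 3.69%) next, and Otc, on X, at 0%. The 13 measured coagulation and complement genes had a mean of 4.11 ± 0.916% against 9.38% in random lists (permutation adjusted p = 0.235). Cfb (13.3 ± 0.898%) was marked, but nearly all of its body lies within another annotated coding gene. Plg (9.73 ± 6.16%) and F10 (9.14 ± 5.29%) followed, and F9 was at 0%.

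Lists of markers of the other cells of the liver had mean coverages of at most 1.03%. Some members did hold peaks. Of 8 macrophage markers, 5 had no covered base in either replicate, and of 9 stem and progenitor markers also 5. Among all protein-coding genes the share without a covered base was 54.6%. No marker of megakaryocytes, lymphocytes, endothelium or stellate cells and mesenchyme was marked in any replicate, and these 4 lists were lower than random lists. Their means were 0.00907 ± 0.0128% (permutation adjusted p = 0.0393), 0% (permutation adjusted p = 0.0156), 0% (permutation adjusted p = 0.00505) and 0.101 ± 0.0696% (permutation adjusted p = 0.00920). The megakaryocyte call was lost without replicate 1, at a mean of 0.0181% (permutation adjusted p = 0.0601), and with a minimum −log10 q of 2, at 0.00907% (permutation adjusted p = 0.0518). Without replicate 2 (permutation adjusted p = 0.0527), with the strongest peaks only and with the authors' replicated list it also missed the threshold, but there its mean was 0%, the lowest possible. The same holds for the lymphocyte list with the strongest peaks only (permutation adjusted p = 0.0611) and with the replicated list (permutation adjusted p = 0.0605). Nor was any marker of the next 4 lists marked, and these passed the threshold in neither direction. They were the markers of granulocytes and monocytes (0.260 ± 0.134%, permutation adjusted p = 0.100), macrophages (1.03 ± 0.587%, permutation adjusted p = 0.0942), haematopoietic stem and progenitor cells (0.401 ± 0.328%, permutation adjusted p = 0.0869) and cholangiocytes (0.0532 ± 0.0752%, permutation adjusted p = 0.0595). The highest values among these 8 lists were those of Vcam1 (5.96 ± 3.90%), Mertk (2.23 ± 0.688%), Csf1r (1.91 ± 1.38%), Runx1 (1.57 ± 1.25%) and Kit (1.24 ± 1.14%).

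Genes of other tissues were lower than random lists. The 12 neuron markers had no covered base (permutation adjusted p = 0.000533). The 12 markers of skeletal and heart muscle were at 0.0186 ± 0.00269% (permutation adjusted p = 0.00141) and the 10 germ line genes at 0.0639 ± 0.0904% (permutation adjusted p = 0.0310), a call that was lost without replicate 1, at a mean of 0.128% (permutation adjusted p = 0.0523). With the strongest peaks only and with the replicated list the germ line genes also missed the threshold, at a mean of 0%. The families of olfactory receptors (0.0315 ± 0.0130%, 1134 genes), vomeronasal receptors (0%, 330 genes), keratins (0.0603 ± 0.0175%, 53 genes) and defensins (0.0305 ± 0.0432%, 64 genes) were lower as well, each at a permutation adjusted p of 0.000533. A single olfactory receptor gene, Olfr419, was marked (33.8 ± 17.6%). Restricted to genes that overlap no other gene, the lower calls of these 4 families held. Those of the 7 cell type lists did not, although their means stayed between 0% and 0.106%, and 4 of these means were 0%, the lowest possible.

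Other gene groups passed the threshold in neither direction. The 11 Hox genes had no covered base, the lowest possible (permutation adjusted p = 0.0676). The 8 replication-dependent histone genes were at 1.11 ± 0.294% (permutation adjusted p = 0.915), with peaks in Hist1h2bc alone. For the histone genes the range of random lists began at 0%, so no lower call could have been made. The 11 measured imprinted genes were at 2.01 ± 0.803% (permutation adjusted p = 0.134), with Igf2r (13.1 ± 2.61%) the only one marked. The family of 394 zinc finger genes had 125 marked members and a mean of 11.3 ± 2.42% against 9.65% in random lists (permutation adjusted p = 0.0676). Its highest members were Zfp869 (86.4 ± 0.966%), Zfp110 (76.1 ± 3.98%) and Zfp335 (71.6 ± 5.35%).

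**Figure D2:**
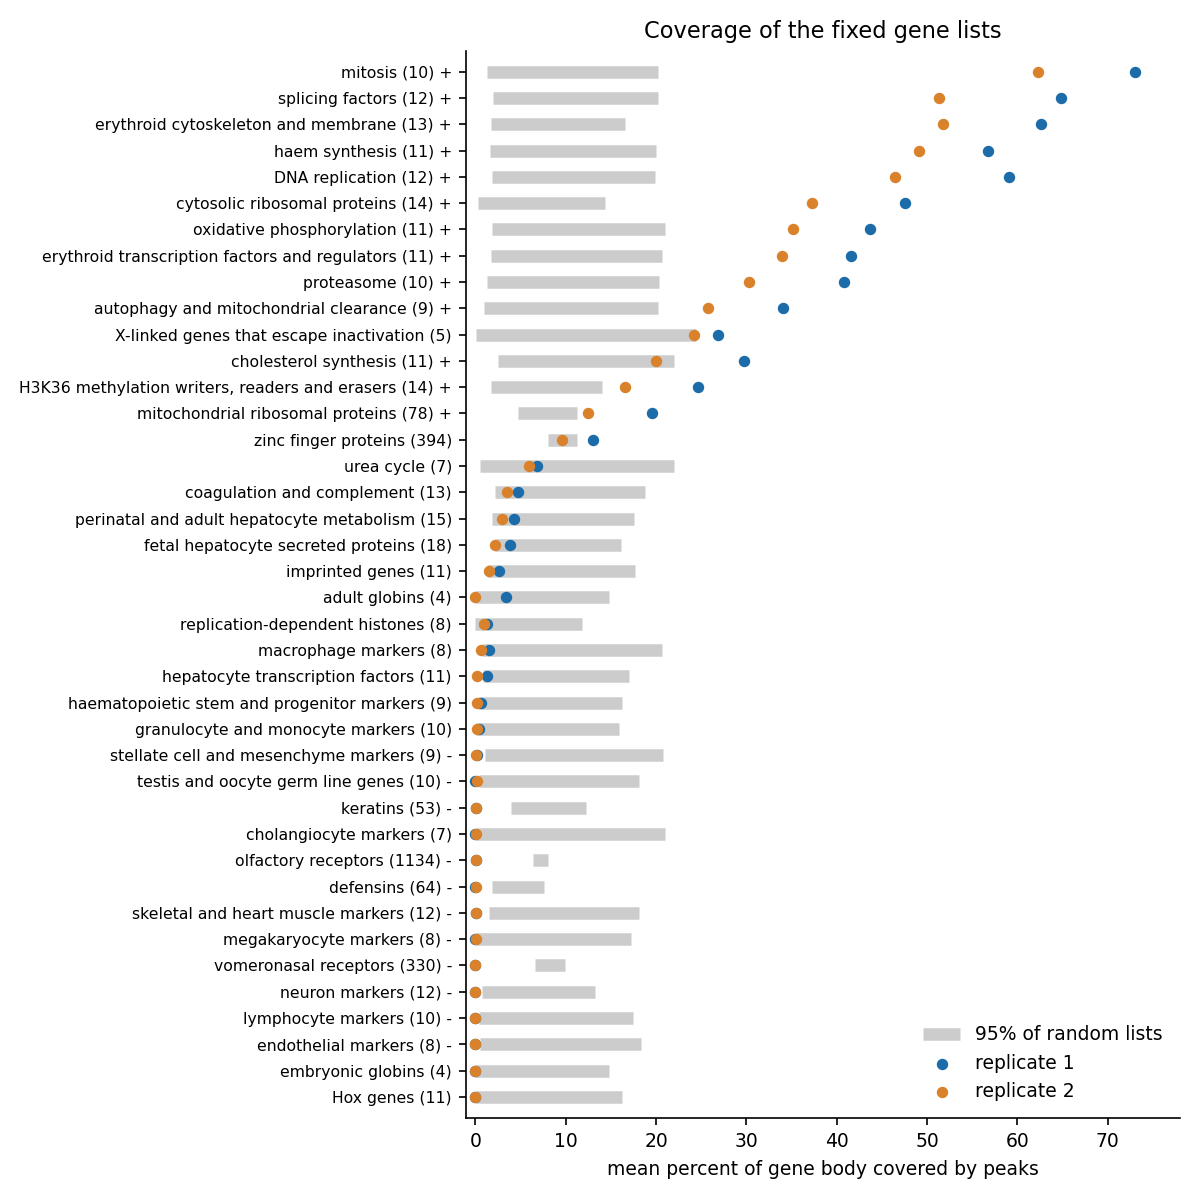
Mean percent of the gene body covered by peaks (x axis) for each fixed gene list or family (y axis, number of measured genes in parentheses). Points are the replicates, and grey bars hold 95% of 10000 random lists of the same size and gene length. A plus marks the 13 sets called higher and a minus the 11 called lower. The mitosis genes lie at 67.7% and the neuron markers at 0%.

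Within genes, the mark lay over the transcribed body and not at the start. Of the covered bases, 95.7% lay in protein-coding gene bodies in each replicate, which make up 40.3% of the sequence, an enrichment of 2.37 (permutation p = 0.001 in each, the smallest that 1000 circular shifts can give). Annotated exons of protein-coding genes, untranslated parts included, held 26.6% of the covered bases in replicate 1 and 28.1% in replicate 2, against 3.72% of the sequence. The 1 kb around transcription start sites held 0.152% and 0.170%, against 0.805% of the sequence. Only 3.62% and 3.67% of the covered bases lay in no annotated gene.

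The shape was measured in 3 ways in the 3203 marked genes of at least 10 kb. The 1 kb around the start site was covered over 0.561% in replicate 1 and 0.486% in replicate 2, against 37.1% and 27.6% of the whole body, a difference of −31.8 ± 6.62 points. Choosing genes by the coverage of their bodies favours this difference. Along 10 equal parts of the gene body, coverage in replicate 1 went from 4.84% in the first part to 52.2% in the ninth and was 47.4% in the last. In replicate 2 it was 3.25%, 40.4% and 36.4% in the same parts. The last 3 parts exceeded the first 3 by 28.8 ± 4.39 points. With bases pooled over genes, internal exons were covered over 65.0% and 52.4% and introns over 31.1% and 22.2%, a difference of 32.0 ± 2.55 points. Each of the 3 differences had the same sign on all 20 chromosomes (two-sided sign-flip permutation p = 1e-05 for each, the smallest that 100000 resamples can give) and was larger than the spread between replicates.

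**Figure D3:**
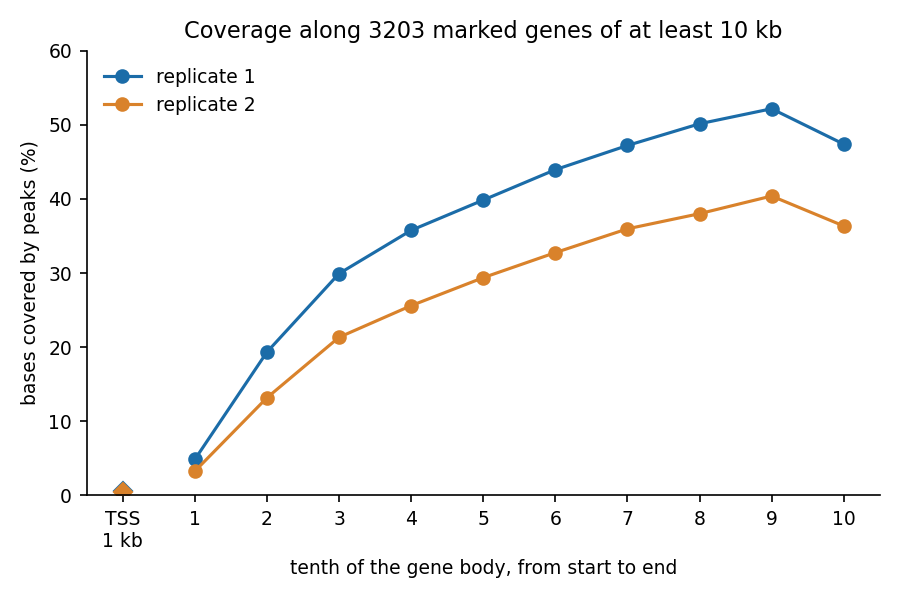
Percent of bases covered by peaks (y axis) in the 1 kb around the transcription start site (diamonds, which overlie each other near 0) and in 10 equal parts of the gene body from start to end (points), mean over 3203 marked genes of at least 10 kb, with a line per replicate. Coverage is highest in the ninth part, at 52.2% in replicate 1 and 40.4% in replicate 2.

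Joined across gaps of at most 3 kb, the authors' replicated peaks formed 15162 domains with a median length of 1.97 kb, of which 2403 reached 10 kb and 63 reached 50 kb. The longest spanned 119 kb of Hectd4, a ubiquitin ligase gene (chromosome 5, 121250746 to 121369423), and 86.4% of it was covered in replicate 1 and 76.5% in replicate 2. It was followed by domains over the ubiquitin ligase gene Ubr4 (101 kb, chromosome 4, 139390230 to 139491565), the chromatin remodeller gene Chd2 (98.3 kb, chromosome 7, 73426819 to 73525151), the erythroid ankyrin gene Ank1 (94.1 kb, chromosome 8, 23055142 to 23149260) and the ubiquitin ligase gene Herc1 (85.3 kb, chromosome 9, 66425286 to 66510593). These numbers depended on the gap and on the list. At a gap of 1 kb there were 27212 domains with a median of 0.814 kb, 1000 of at least 10 kb and 8 of at least 50 kb. At 10 kb there were 8380 with a median of 6.83 kb, 3495 and 431. At 3 kb, domains of at least 50 kb numbered 142 in replicate 1 alone, 71 in replicate 2 alone and 109 in the pooled list. The replicated peak with the highest fold enrichment, 22.02 as given by the authors, lay wholly within Trim56 (chromosome 5, 137112454 to 137115287), and 83.7% of it was exonic. The next 4 lay in the splicing gene Srrm2 (fold 18.4, chromosome 17, 23814538 to 23821426), the tropomyosin gene Tpm1 (fold 17.8, chromosome 9, 67031461 to 67036552), Zfp68 (fold 16.2, chromosome 5, 138610618 to 138612259) and the neighbouring genes Tmem259 and Grin3b (fold 15.6, chromosome 10, 79975421 to 79979490). Exons made up 91.5% of the peak in Srrm2, 22.1% in Tpm1, 13.2% in Zfp68 and, by the exons of Tmem259, 86.3% of the last.

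The X chromosome was covered less than every autosome. Peaks covered 0.917 ± 0.202% of the bases of X-linked protein-coding gene bodies and 4.38 ± 1.04% of those on the autosomes, a difference of −3.47 ± 0.836 points. The lowest autosome, chromosome 14, was at 2.83 ± 0.759% and the highest, chromosome 11, at 6.47 ± 1.48%. X was the lowest of 20 chromosomes, for which the exact permutation p is 0.05, the smallest that a rank among 20 can give, so the test cannot go below the threshold of 0.05. Of 948 coding genes on X, 37 were marked (3.90%). Of the 5 measured genes that escape X inactivation, the process that silences 1 of the X chromosomes of females, 3 were marked. The list had a mean of 25.5 ± 1.92% (permutation adjusted p = 0.0595), and was higher than random lists under 4 alternatives, including without replicate 1 (24.2%). Kdm5c was covered over 47.3 ± 3.26%, Ddx3x over 34.9 ± 2.41% and Eif2s3x over 33.5 ± 3.30%, and the lowest was Kdm6a (4.00 ± 0.381%). The erythroid genes Alas2 and Gata1 also lie on X, with coverages of 44.5 ± 11.7% and 12.3 ± 3.58%.

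**Figure D4:**
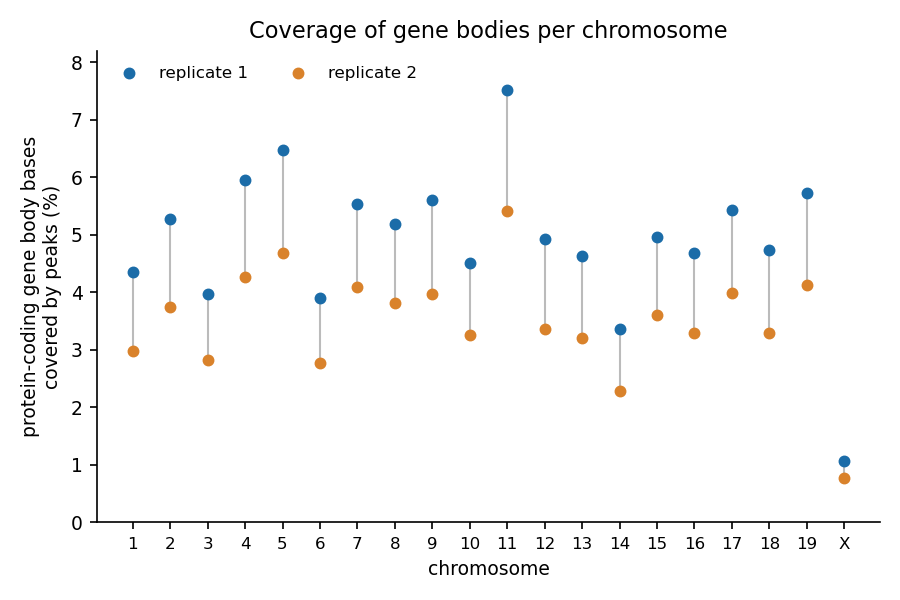
Percent of protein-coding gene body bases covered by peaks (y axis) on each chromosome (x axis). Points are the replicates, joined by a grey line. X lies at 1.06% in replicate 1 and 0.775% in replicate 2, and chromosome 11 at 6.47% on average.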

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

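The tests of explanations here were fixed before the values they measure were seen, except the combined test of exons and introns, the tests on genes that overlap no other gene or have no covered neighbour, the exon test on windows with few masked bases alone, the label shuffle of uncorrected values, the fold of peaks in gene sets and the comparison of marked genes on X, which were chosen after. The patterns themselves were seen first.

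Signals appeared in sequence that the report's measures of genes did not use. The authors' replicated list held 3 peaks on chromosome Y, all between 90738685 and 90745861 and in no annotated gene, with folds of 6.54, 10.4 and 2.05. It also held 5 peaks on unplaced or unlocalized scaffolds, the strongest with a fold of 9.85. Of 9192 non-coding genes of at least 1 kb that touch no coding gene, 41 (0.446%) had at least 10% of the body covered in both replicates.

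Genes of the erythroid lists were covered far more than those of the hepatocyte lists. The lists differ in kind, since the erythroid ones include haem synthesis and the hepatocyte ones include perinatal and adult metabolism. How far the members of either are restricted to a cell type or stage was not tested. The 35 genes of the 3 erythroid lists had a mean coverage of 49.8 ± 6.23% (SD, n = 2) and the 64 genes of the 5 hepatocyte lists one of 3.34 ± 0.941%, a difference of 46.4 points (permutation p = 1e-05 over genes, the smallest that 100000 shuffles can give). Gene length, GC content and repeats do not account for it, since 46.1 points were left when each gene was set against genes in the same of 5 equal classes of each property (permutation p = 1e-05). A candidate explanation that stays open is that hepatocytes are too few in the pooled tissue for their marked genes to pass the peak threshold in full. It predicts traces of signal, and 33 of 64 hepatocyte genes held a peak in at least 1 replicate, against 3 of 34 neuron, muscle and germ line genes, a difference of 42.7 points (Fisher's exact p = 1.96e-05; 18 of 43 against 1 of 13 among genes that overlap no other gene, Fisher's exact p = 0.0416). Of all 21728 protein-coding genes, however, 54.6% had no covered base. The share of hepatocyte genes with a peak, 51.6%, was thus near that of all coding genes. The traces therefore cannot tell a thinned hepatocyte signal from the level of coding genes at large. Peaks can also run on from a neighbouring gene, and among genes with no other coding gene that holds a peak within 10 kb, 11 of 34 against 2 of 24 held a peak (Fisher's exact p = 0.0529), so run-on from neighbours is not excluded as the source of part of the traces. Peaks in hepatocyte genes had a median fold of 3.61 in replicate 1 and 3.46 in replicate 2, against 4.62 and 4.27 in erythroid genes and 3.49 and 5.18 in neuron, muscle and germ line genes, which held 2 and 3 peaks. Lower marking of these genes within hepatocytes was not tested, since the series has no sorted cells or second stage.

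X-linked genes were covered over 0.917% against 4.38% on autosomes. Repeats do not account for it, since over unmasked bases X was at 1.14 ± 0.246% and the lowest autosome at 3.18%. Nor does the gene content of X as far as promoters show it: among genes with CpG-rich promoters 11.7 ± 1.91% on X were marked, against 32.5% to 45.0% on the autosomes. Fewer reads on X, of which males carry a single copy, stay open. At the same p the fold of X peaks was 1.03 ± 0.0112 times that of autosomal peaks, above each autosome (0.996 to 1.01). That is the direction a lower background would give, but the size it would give was not worked out. Whether fewer reads could account for a difference in coverage of this size was therefore not tested. The 37 marked genes on X had a mean coverage of 27.2 ± 4.84% and the 4263 on autosomes one of 33.2 ± 6.46%, and silencing of 1 X in females, which the pools do not separate, was not tested.

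Internal exons were covered more than introns by 32.0 points. The difference was above 0 on every chromosome over unmasked bases (24.3 points on the lowest), within 10 equal parts of the gene body (23.4 points) and against intron windows of the same GC content (23.5 points), so repeats, position and GC content are each argued against as its whole cause. With all 3 held together, in windows with under 10% masked bases, 21.3 ± 2.17 points remained (17.6 on the lowest chromosome), against 28.3 ± 2.52 points in the same kind of window with position and GC content left free, so these 2 go with part of it. Bases were pooled over the genes of a chromosome and were not compared within each gene. A part that comes from which genes hold most exon bases and which most intron bases was therefore not separated. A biological hypothesis that also remains is a higher level of the mark, or of nucleosomes, on exons, and occupancy of nucleosomes was not measured here.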

How the results depend on the processing

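Of the 78 alternative values of the main results, 71 kept their result and none reversed. Kept means the same direction and side of the threshold for a tested value, a change within 1 SD of the replicates for the covered length, and a change of at most 1.5 times for a count. A single replicate of a pair always lies within 1 SD of their mean. For the covered length, the alternatives of each replicate alone were therefore bound to be kept. Under this rule marked genes count as kept at 2890 with the strongest peaks only and domains at 20310 in replicate 2 alone. The differences at the start site (−27.0 to −41.8 points), along the body (24.0 to 37.8) and between exons and introns (29.7 to 34.8) kept direction and threshold under each alternative run, and the enrichment in gene bodies was 2.37 to 2.38. X stayed lowest in the alternatives ranked, at −2.39 to −5.14 points from the autosomes, with the permutation p at its smallest possible value. Shared peaks stayed above the shifted placements, also at the smallest possible p, but the shares themselves changed. They were 30.7% to 57.2% for replicate 1, and 34.4% to 74.5% for replicate 2, lowest where 50% of both peaks had to overlap. Genes chosen in the other replicate, added after seeing the data, gave −29.7 points for the start site, 27.0 for the gradient and 31.2 for exons minus introns. On unmasked bases, also added later, exons minus introns was 30.2 points and X minus autosomes −3.76 points.

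By the rule above, which leaves the shares out, the values that moved were the covered length and counts. With the strongest peaks only, the covered length was 29.8 Mb, as fewer peaks entered. Domains numbered 27212 at a gap of 1 kb and 8380 at 10 kb. Marked genes numbered 8541 at any overlap and 2083 at 25%. With list medians, 15 sets passed the threshold, all higher. The 11 sets lower in the main result each had a median of 0%, the lowest possible, and a permutation adjusted p of 1, so medians say nothing about them. With genes that overlap no other gene, 14 sets passed (10 higher and 4 lower), with fewer genes in each list.

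For single sets, 346 of 400 alternative values kept the call, 40 lost it and 14 gained one. In 29 of the 40 losses the value was 0%, the lowest possible, so no lower call could have been made there. These were 11 with medians, 7 with the share of marked members and 11 others. No paired analysis was possible because the series has 1 group. Depth is unknown, so a gene without a peak is one in which the mark was not detected, not one that lacks it.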

Other observations

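The values here were chosen after the data were seen. Coverage went on beyond the annotated ends of genes. In 347 marked genes of at least 10 kb with no other gene within 10 kb on either side, the first kb after the annotated end was covered over 29.5% in replicate 1 and 20.3% in replicate 2, and the tenth kb over 0.282% and 0.330%. Over the 10 kb after the end the mean was 4.93 ± 1.29% (SD, n = 2), and over the 10 kb before the start it was 0.0294 ± 0.00391%.

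Some marked members of lists that otherwise held few peaks lie beside genes that are more covered. Slc10a1, the bile acid transporter, ends 2675 bp from the end of the splicing factor gene Srsf5 on the other strand, which was covered over 56.1 ± 9.11%. Of 10 equal parts of Slc10a1, the last 3 were covered over 90.9% and the first 3 over 0%. Olfr419 ends 63 bp from the end of the spectrin gene Spta1, which was covered over 58.7 ± 11.9%. The coding gene nearest to Igf2r, the marked imprinted gene, is Slc22a1 at 6576 bp, which was at 0%. Apoe was covered over 0% in its first 3 parts and over 60.2% in its last 3. Its nearest coding gene, Tomm40 at 2124 bp, was at 24.3 ± 2.77%, close to the 21.4% of Apoe itself. Asl (11.6%) lies 42 bp from Crcp, which was at 17.3 ± 2.77%. Cfb (13.3%) was covered over 0% in its first 3 parts and over 38.0% in its last 3. Of its body, 99.4% lies within Gm20547 on the same strand, which was at 3.11 ± 0.320%. These values share bases, so Gm20547 cannot serve as a separate neighbour, and the next gene was not looked at.

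The covered non-coding genes of at least 1 kb outside coding genes included several known RNAs. Malat1, an abundant nuclear RNA (chromosome 19, 5795690 to 5802672), was covered over 65.4 ± 3.12%, the snoRNA host gene Snhg1 over 68.7 ± 0.476% and the microRNA host gene Mir17hg over 61.8 ± 10.4%. Of the 41, 22 are annotated as long intergenic RNAs.

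The excess of replicate 1 over replicate 2 was looked at by gene list, against random lists of the same mean coverage. Of 21 sets with at least 5 covered genes, none passed a Benjamini-Hochberg adjusted p of 0.05 in this permutation test, and 2 had an unadjusted p below 0.05. These were the hepatocyte transcription factors (2.01 points against 0.431 in random lists, adjusted permutation p = 0.147) and the mitochondrial ribosomal proteins (7.78 points against 6.17, adjusted permutation p = 0.147).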
